A study of Mus musculus with 24 samples.

How the data were processed

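Total RNA from the hypothalamus of C57BL6 mice was sequenced after stranded library preparation, per the labels' protocols. The mice were 15 months old and had eaten 1 of 4 diets from 12 weeks of age. The diets held branched-chain amino acids (BCAA: leucine, isoleucine and valine) at 20, 50, 100 or 200% of the standard content and are called BCAA20, BCAA50, BCAA100 and BCAA200. Each diet had 3 females and 3 males, so that 24 libraries formed 8 groups. Replicate numbers 1 to 3 are females and 4 to 6 are males in the labels.

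The values are FPKM per gene symbol and library, as the authors deposited them. TopHat2 2.0.14, StringTie 1.2.4 and the genome build GRCm38 are named per the submitters' processing notes, which give them no role or order. The annotation release is not given in the sources used here. The deposited table held 18777 gene symbols and 2 further rows, both with the BCAA intake of each animal, whose unit is not stated. The authors also deposited a Pearson correlation coefficient of each gene's FPKM with intake, and its unadjusted p-value. Every column of the table was matched to a library or to these 2 statistics. None of the 15 mitochondrially encoded genes was listed under its symbol, and the rows with the highest mean FPKM were predicted genes such as Gm29216, with a mean of 8290 FPKM.

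FPKM values give no read depth. In 473 genes of low level, 11.2% of 3307 values lay within 5% of a whole multiple of the gene's smallest value, against 10% for evenly spread values. The multiples were taken across libraries, where whole reads need not give whole multiples if depths differ. The values therefore cannot decide whether whole reads could be recovered, and the depth of each library is unknown. Columns summed to between 293850 and 328809 FPKM. No pair of libraries held identical values. Correlations of log2 values across genes, which are not independent replicates, ranged from 0.912 to 0.969 within groups and from 0.886 to 0.967 between groups.

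Values were analysed as log2(FPKM + 0.5), for 13806 genes with a mean of at least 1 FPKM over all libraries. A fold change on this scale understates the change of genes with low values. Linear models with 8 group means were fitted with limma 3.58.1 in R 4.3.3, with a mean-variance trend and robust moderation, on 16 residual degrees of freedom. Diet contrasts averaged the female and male contrasts. Dose trends are slopes per doubling of the BCAA content. Genes passed at a Benjamini-Hochberg adjusted p under 0.05, and tests were two-sided. Of 36 gene lists, 34 had at least 5 measured members. They were tested with camera at a preset inter-gene correlation of 0.01, with the estimated correlation and fry as alternatives. The mitochondrially encoded genes and the pituitary markers had 0 and 2 measured members and were not tested.

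The design, the gene lists and a rule for the genes named were fixed before the data were examined. The rule takes up to 10 genes per direction with the largest change among those past the threshold, or the 5 per direction with the lowest unadjusted p where none passed. In BCAA200 against BCAA20 and the lane 1 trend, it adds members of the fixed lists that passed when adjusted over the list alone (at most 4 per list). It also takes a fixed set of feeding, serotonin, BCAA and sex-linked genes. Predicted genes were counted and not named, and 1 gene that the rule takes is not reported here. Gene positions are from GENCODE M21 on GRCm38, in which 13561 of the 13806 symbols were found. How reads of overlapping genes or close paralogs were assigned is not given in the sources used here, so values of such genes are uncertain.

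All 6 BCAA100 libraries were sequenced in lane 2 and the other 18 libraries in lane 1, per the labels. The sample titles also name the BCAA100 animals Chow, with numbers apart from those of the other diets. Comparisons with BCAA100 are therefore confounded with the lane and with any other difference of that group. BCAA200 against BCAA20 and the trend over the lane 1 diets lie within a lane. The pipeline was tested on simulated data: with 13806 genes and 50 changed genes per size in BCAA200 against BCAA20, 36% were recovered at a log2 change of 0.5, 92% at 1, 96% at 2 and 100% at 3, with 12 false calls among 174. The simulated genes varied independently, which the real genes do not. All sizes were changed in the same simulated set, and many changed genes ease the Benjamini-Hochberg threshold. The shares recovered therefore do not hold where few genes change.

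Alternatives were other pseudocounts, filters, scaling and sample weights, a fit on the groups compared, a replicate block, leaving out each library, other dose scales and other list tests. Regional marker scores (cortex and hippocampus, thalamus, striatum and hypothalamic nuclei) as covariates, and leaving out 4 doubted libraries, were added after seeing the data. The doubted libraries have a sex label that differs from their sex-linked genes, or Slc17a7 under 20 FPKM. Low Slc17a7 does not by itself mark a library as faulty, so the fit without them need not be a cleaner one.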

Results

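Hypothalamic expression was measured in 24 mice on diets of equal energy (14.4 MJ/kg) with 18.8% protein, 63.4% carbohydrate and 17.8% fat. The diets differed in their content of BCAA, and the study concerned amino acid balance and appetite. BCAA intake formed 4 clusters that did not overlap. It averaged 0.417 ± 0.0344 (SD, n = 6) on BCAA20, 1.01 ± 0.0808 on BCAA50, 2.12 ± 0.272 on BCAA100 and 5.26 ± 0.559 on BCAA200, in a unit that was not stated. Divided by the relative BCAA content of the diet, intake was 2.08 ± 0.172 on BCAA20, 2.02 ± 0.162 on BCAA50, 2.12 ± 0.272 on BCAA100 and 2.63 ± 0.280 on BCAA200 (SD, n = 6). The BCAA200 value was 1.24 times that of BCAA100 (exact permutation p = 0.0152, adjusted p = 0.0253 over 5 comparisons). It was also higher than on BCAA20 and on BCAA50 (exact permutation p = 0.00649, adjusted p = 0.0162 for each).

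**Figure D1:**
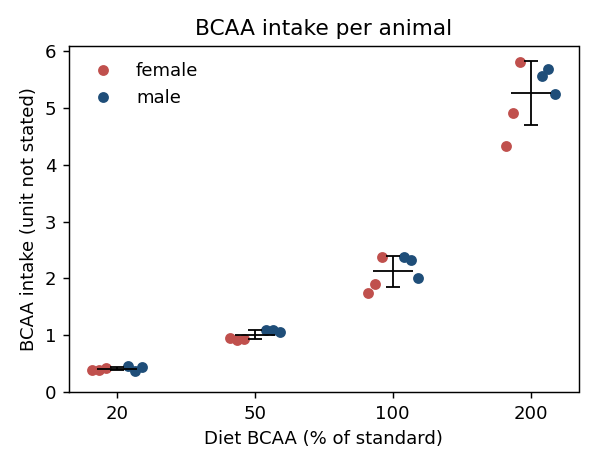
BCAA intake of each animal (vertical axis, unit not stated) by BCAA content of the diet (horizontal axis, % of standard). Points are animals, bars the mean and SD of 6 animals. The 4 diets did not overlap, with BCAA200 between 4.33 and 5.81 and BCAA100 between 1.75 and 2.38.

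The libraries differed in markers of neighbouring brain regions. Slc17a7, a vesicular glutamate transporter abundant in cortex, was at 6.23 FPKM in BCAA50 female replicate 1, 3.99 in BCAA100 male replicate 5 and 12.6 in BCAA100 male replicate 6, and above 105 in every other library. The score of the hypothalamic nuclei markers was highest in BCAA100 male replicate 5 (1.627), followed by BCAA50 female replicate 1 (1.19). It was -1.145 in BCAA100 male replicate 6. Low Slc17a7 therefore does not show that a library held less hypothalamus. The first principal component held 18.4% of the variance. Diet accounted for a median of 11.1% of a gene's variance, against 11.3% on average with 100 shuffles of the diet labels. The 4 regional marker scores accounted for a median of 33.5%, with 4 terms against 3 for diet. These scores were computed from the same expression values, which raises their share, and were not shuffled. The shares of the scores and of diet are therefore not measured alike.

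**Figure D2:**
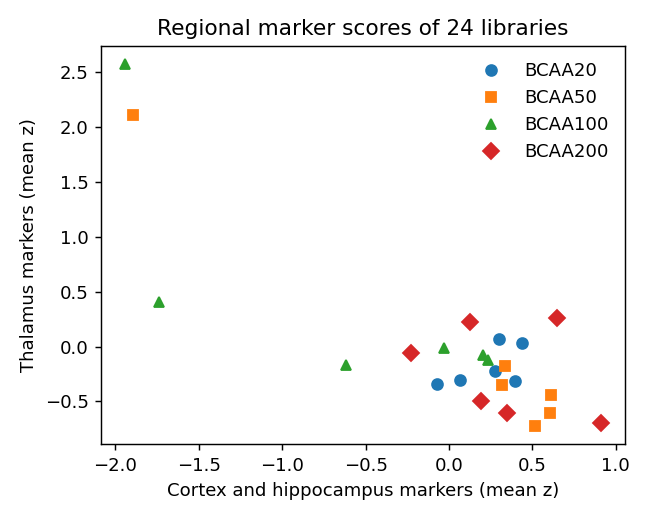
Mean z score of the thalamus markers (vertical axis) against that of the cortex and hippocampus markers (horizontal axis), 1 point per library, with diets by symbol. 3 libraries lie at cortex and hippocampus scores of -1.894, -1.737 and -1.941, apart from the other libraries.

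The comparison of the highest with the lowest BCAA content, BCAA200 against BCAA20, lies within lane 1. Fos, an immediate early gene, was 12.2 ± 3.19 FPKM on BCAA200 and 20.2 ± 1.52 on BCAA20 (SD, n = 6). Its log2 change was -0.75 (SE 0.194) and it passed when adjusted over the list alone (limma adjusted p = 0.0231), not over all genes. The adjustment over a list alone was made within each list, with no correction over the 34 lists. Only the immediate early and glucocorticoid response lists held members that passed it in this comparison. Of the 16 measured glucocorticoid response genes, 3 were higher when adjusted over the list alone, and none over all genes. They were Zbtb16, a transcription factor (6.33 ± 1.71 against 2.85 ± 0.880 FPKM, limma adjusted p = 0.0116), Plin4, a lipid droplet protein (2.05 ± 0.994 against 0.622 ± 0.1995 FPKM, limma adjusted p = 0.0116), and Fkbp5, a co-chaperone of the glucocorticoid receptor (7.53 ± 0.734 against 5.32 ± 0.649 FPKM, limma adjusted p = 0.0309). Fkbp5 overlaps 4 annotated genes, 2 of them on its own strand, and its values are uncertain to that extent.

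Across all genes, none passed in BCAA200 against BCAA20 with limma, and 399 had an unadjusted p under 0.05, where chance gives 690. Without BCAA20 male replicate 5, 1 gene passed. The lowest unadjusted p among genes with higher values were those of Ttc7b (log2 change 0.30, SE 0.0664), Abcg2 (1.495, SE 0.385), Plin4, St6gal1 (1.76, SE 0.459) and Zbtb16. Among genes with lower values they were those of Anapc4 (-0.96, SE 0.204), Mettl14 (-0.83, SE 0.186), Ddhd1 (-0.80, SE 0.199), Ercc2 (-0.42, SE 0.109) and Fos. Anapc4 encodes a subunit of the anaphase-promoting complex and lies on chromosome 5 at 52834012 to 52867797 (GRCm38), where no other annotated gene overlaps it.

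**Figure D3:**
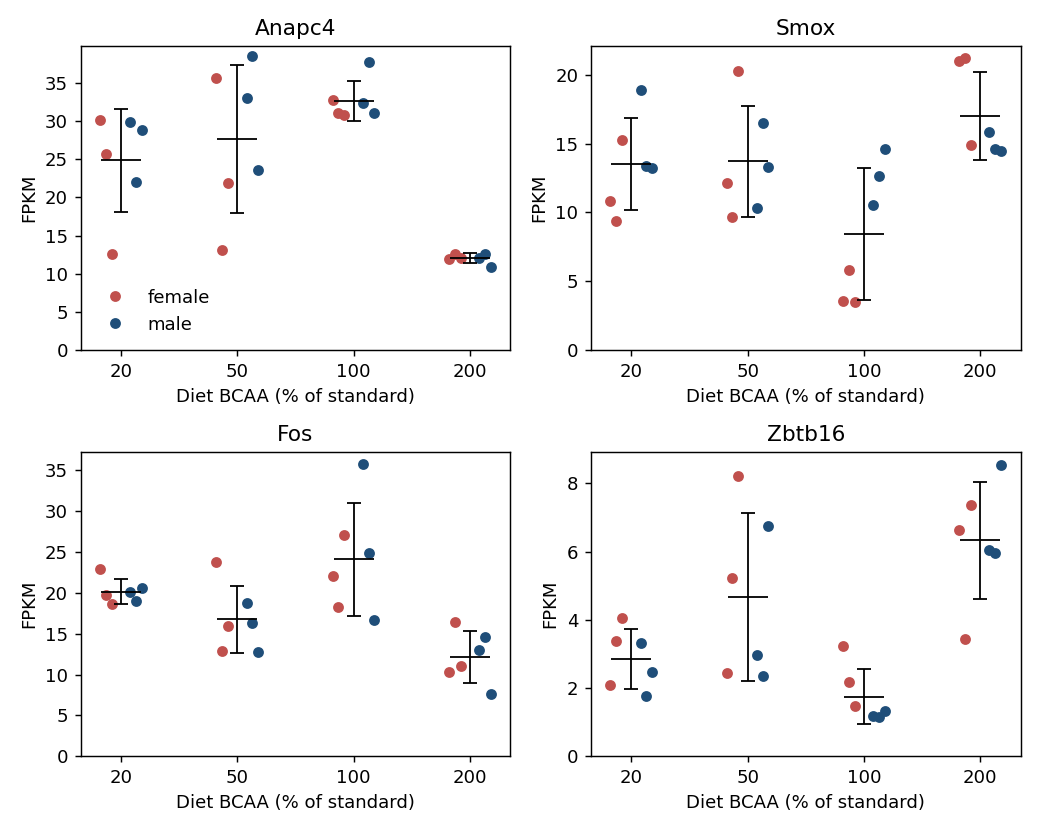
FPKM (vertical axes) of Anapc4, Smox, Fos and Zbtb16 by BCAA content of the diet (horizontal axes, % of standard). Points are libraries, bars the mean and SD of 6 libraries. Anapc4 lay between 10.9 and 12.6 FPKM in the BCAA200 libraries.

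Genes of appetite control varied widely between libraries. Npy was 50.8 ± 14.4 FPKM on BCAA200 and 43.1 ± 12.2 on BCAA20 (SD, n = 6). Pomc was 5.85 ± 8.77 and 6.88 ± 5.09 FPKM, Hcrt 29.3 ± 16.2 and 28.1 ± 9.85, and Pmch 167 ± 80.8 and 162 ± 39.3. Agrp was 0.134 ± 0.136 and 0.246 ± 0.306 FPKM, below the filter. None of the 33 measured feeding neuropeptides and receptors had an unadjusted p under 0.05 in BCAA200 against BCAA20, and none passed when adjusted over the list alone. The same held for the 15 measured serotonin signalling genes, among them Htr2c (21.6 ± 2.85 against 22.9 ± 2.06 FPKM) and Htr1b (6.34 ± 2.39 against 6.15 ± 1.53 FPKM). It held also for the 27 BCAA catabolism genes, among them Bckdk, the kinase of the BCAA dehydrogenase (8.32 ± 0.690 against 8.69 ± 0.964 FPKM), and for the 45 mTORC1 amino acid sensing genes.

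Of 34 gene lists, 10 were called in BCAA200 against BCAA20 by camera with the preset correlation, 6 up and 4 down. None was called with an estimated correlation, where the lowest adjusted p was 0.863, and none by fry. Cholesterol biosynthesis genes had 22 of 24 members below 0 with a median log2 change of -0.109 (camera adjusted p = 7.62e-05; adjusted p = 0.863 with an estimated correlation). Immediate early genes had 17 of 20 members below 0 (camera adjusted p = 0.00625; adjusted p = 0.946 with an estimated correlation), and amino acid response genes 26 of 39 (camera adjusted p = 0.0196; adjusted p = 0.94 with an estimated correlation). Striatum markers had 14 of 14 members above 0 (camera adjusted p = 0.0179; adjusted p = 0.946 with an estimated correlation). Choroid plexus markers had 6 of 6 above 0 (camera adjusted p = 0.0186) and blood markers 6 of 6 below 0 (camera adjusted p = 0.0179), both with an adjusted p = 0.94 with an estimated correlation. The glucocorticoid response list had 10 of 16 members above 0 and microglia markers 11 of 15 (camera adjusted p = 0.0155 for both; adjusted p = 0.94 with an estimated correlation). Tanycyte and ependyma markers had 9 of 11 above 0 (camera adjusted p = 0.0432; adjusted p = 0.946 with an estimated correlation), and dopamine signalling 9 of 9 (camera adjusted p = 0.0196; adjusted p = 0.863 with an estimated correlation). The median and the test differed in sign for 5 of the 34 lists, none of them called. Without BCAA200 female replicate 3, 1 list was called, without BCAA200 female replicate 1, 3 lists, without BCAA20 female replicate 1, BCAA20 male replicate 4 or BCAA200 male replicate 6, 4 lists, and without BCAA20 female replicate 2, 6 lists.

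The dose trend over the 3 lane 1 diets called no gene with limma, and 391 genes had an unadjusted p under 0.05. Anapc4 had a slope of -0.31 (SE 0.0611, limma adjusted p = 0.959) and Ttc7b 0.09 (SE 0.0199). Fos (-0.22, SE 0.0581), Plin4 (0.34, SE 0.0866), Zbtb16 (0.30, SE 0.0823) and Fkbp5 (0.14, SE 0.0448) passed when adjusted over the list alone and not over all genes. Without BCAA20 female replicate 3, Anapc4 passed over all genes, with a slope of -0.36 (limma adjusted p = 0.0356), and without BCAA20 male replicate 5, 1 gene passed. Anapc4 also passed with array weights (slope -0.32, limma adjusted p = 0.0451). Camera with the preset correlation called 10 of 34 lists in this trend, among them cholesterol biosynthesis with 22 of 24 members below 0 (camera adjusted p = 1.79e-05; adjusted p = 0.782 with an estimated correlation). Over all 4 diets no gene passed with limma, and 328 had an unadjusted p under 0.05. In that trend no immediate early gene or glucocorticoid response gene passed when adjusted over the list alone. Without BCAA20 male replicate 5 or BCAA100 female replicate 2, 1 gene passed. In the authors' deposited table, 518 of 18777 genes had an unadjusted p under 0.05 for the correlation with intake, where chance gives 939, and none passed Benjamini-Hochberg adjustment. Its lowest p was that of Ttc7b (Pearson R 0.742).

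Comparisons with the standard content cannot be separated from the lane, or from other differences of the animals that the titles name Chow. In BCAA200 against BCAA100, Smox, which encodes spermine oxidase and lies on chromosome 2 at 131491496 to 131525922 (GRCm38), was 17.0 ± 3.21 against 8.44 ± 4.80 FPKM (SD, n = 6). Its log2 change was 1.15 (SE 0.180, limma adjusted p = 0.0296). Smox on BCAA100 was 4.29 ± 1.31 FPKM in females and 12.6 ± 2.02 in males (SD, n = 3). Anapc4 was 12.0 ± 0.640 against 32.6 ± 2.61 FPKM (log2 change -1.40, SE 0.204, limma adjusted p = 0.0233). No other gene passed, and 1618 had an unadjusted p under 0.05. Cortex and hippocampus markers had 13 of 14 members above 0 (camera adjusted p = 1.12e-10; adjusted p = 0.513 with an estimated correlation), and the 3 libraries with low Slc17a7 include 2 of the 6 BCAA100 libraries. Without the 4 doubted libraries 49 genes passed, 33 of them lower on BCAA200. Dlx1, Sall1, Gpsm1 and Frmd7, among the lower ones, were also called lower in BCAA20 and in BCAA50 against BCAA100 without these libraries. The calls of these named genes set BCAA100 apart from all other diets and do not follow the BCAA content. Others were called in BCAA200 against BCAA100 alone. Among them were Fos (log2 change -1.22, limma adjusted p = 0.0175) and Zbtb16 (1.64, limma adjusted p = 0.0476). The cause of these calls was not tested. Without BCAA50 female replicate 1, 41 genes passed. With regional marker scores as covariates none passed: Smox had a log2 change of 1.12 (limma adjusted p = 1) and Anapc4 -1.55 (limma adjusted p = 0.326). Smox did not pass with array weights (limma adjusted p = 0.071) or with the replicate block (limma adjusted p = 0.239). Both calls were lost without BCAA100 female replicate 1 or 3, BCAA200 female replicate 1, or BCAA200 male replicate 4, 5 or 6. The call of Smox was also lost without BCAA20 female replicate 1, BCAA100 male replicate 4 or BCAA200 female replicate 2. Without BCAA100 male replicate 5, 6 genes passed, and without BCAA50 male replicate 5 or 6, 4 genes passed.

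Among the lists in BCAA200 against BCAA100, camera with the preset correlation called 8 of 34, 3 up and 5 down, and none with an estimated correlation. Cholesterol biosynthesis had 21 of 24 members below 0 (camera adjusted p = 0.000917; adjusted p = 0.717 with an estimated correlation), with 5 lower when adjusted over the list alone. BCAA catabolism had 23 of 27 members below 0 (camera adjusted p = 0.0184), with 3 lower when adjusted over the list alone. More strongly called were nuclear oxidative phosphorylation (63 of 74 below 0, camera adjusted p = 6.28e-05) and cytosolic ribosomal proteins (71 of 79, camera adjusted p = 0.00839). Microglia markers had 11 of 15 above 0 (camera adjusted p = 0.000891) and meninges and fibroblast markers 11 of 12 (camera adjusted p = 0.00103). Each of these had an adjusted p = 0.717 with an estimated correlation. The median log2 change over all genes was -0.051. Oligodendrocyte and myelin markers had 16 of 16 members below 0 (camera adjusted p = 0.00399; adjusted p = 0.717 with an estimated correlation). Adjusted over the list alone, 9 cortex and hippocampus markers and 5 glucocorticoid response genes were higher, and 7 GABA signalling genes and 1 glucocorticoid response gene lower. The GABA signalling and glucocorticoid response lists were not called (camera adjusted p = 0.176 and 0.141; adjusted p = 0.717 for both with an estimated correlation). None of the members of these lists passed over all genes with all libraries kept. In BCAA200 against BCAA20, within lane 1, BCAA catabolism (camera adjusted p = 0.629) and oligodendrocyte markers (camera adjusted p = 0.575) were not called. The 3 comparisons with BCAA100 share its libraries, so their list results are not independent.

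No gene passed in BCAA20 against BCAA100 with limma, and 979 had an unadjusted p under 0.05. Mthfsd had the lowest p (10.2 ± 1.54 against 5.995 ± 0.559 FPKM, log2 change 0.71, limma adjusted p = 0.129). Mccc2, a subunit of an enzyme of leucine breakdown, had a log2 change of -0.37 (SE 0.0841, limma adjusted p = 0.454). Smox had a log2 change of 0.81 (SE 0.180). Mthfsd passed without BCAA20 female replicate 2 (limma adjusted p = 0.0468) or BCAA50 male replicate 6 (limma adjusted p = 0.0346). Without BCAA20 female replicate 2, 2 genes passed, without BCAA20 male replicate 5, BCAA50 female replicate 1, BCAA50 male replicate 6 or BCAA100 female replicate 2, 1 gene passed, and without the 4 doubted libraries 5 genes passed. Cortex and hippocampus markers had 13 of 14 members above 0 (camera adjusted p = 2.16e-10; adjusted p = 0.553 with an estimated correlation) and feeding neuropeptides and receptors 21 of 33 (camera adjusted p = 0.0256; adjusted p = 0.823 with an estimated correlation). BCAA catabolism had 22 of 27 members below 0 (camera adjusted p = 0.0325) and oligodendrocyte and myelin markers 16 of 16 (camera adjusted p = 0.00949). More strongly called were nuclear oxidative phosphorylation (63 of 74 below 0, camera adjusted p = 3.29e-05) and cytosolic ribosomal proteins (66 of 79, camera adjusted p = 0.00698). Blood markers had 5 of 6 above 0 (camera adjusted p = 0.000192) and meninges and fibroblast markers 11 of 12 (camera adjusted p = 0.000378). Each of these had an adjusted p = 0.823 with an estimated correlation. Of 34 lists 10 were called, 5 up and 5 down, and none with an estimated correlation (lowest adjusted p = 0.553) or by fry.

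In BCAA50 against BCAA100 no gene passed with limma, and 1056 had an unadjusted p under 0.05. Gpr17, a receptor of oligodendrocyte precursors, was 10.1 ± 1.17 against 7.34 ± 0.773 FPKM (log2 change 0.44, limma adjusted p = 0.285), and Smox had a log2 change of 0.82. Without BCAA50 female replicate 1, 23 genes passed, among them Gpr17 (limma adjusted p = 0.0458), and without the 4 doubted libraries 19. Without BCAA50 female replicate 2, BCAA50 male replicate 6 or BCAA100 female replicate 2, 1 gene passed. BCAA catabolism had 22 of 27 members below 0 (camera adjusted p = 0.0291). More strongly called were nuclear oxidative phosphorylation (66 of 74 below 0, camera adjusted p = 0.000514) and cytosolic ribosomal proteins (68 of 79, camera adjusted p = 0.00935). Each of these had an adjusted p = 0.881 with an estimated correlation. Cortex and hippocampus markers had 14 of 14 above 0 (camera adjusted p = 2.46e-08) and striatum markers 14 of 14 below 0 (camera adjusted p = 0.0397), both with an adjusted p = 0.881 with an estimated correlation. Oligodendrocyte and myelin markers had 16 of 16 below 0 and were not called (camera adjusted p = 0.49). Of 34 lists 9 were called, 3 up and 6 down, and none with an estimated correlation (lowest adjusted p = 0.881).

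Between the sexes, 9 genes passed with limma, 3 higher in males and 6 higher in females. The Y-linked genes Ddx3y (log2 change 4.42), Eif2s3y (4.31) and Kdm5d (2.36) were higher in males, each with a limma adjusted p of 2.17e-06. Xist, the RNA of the inactive X chromosome, was higher in females (-7.05, limma adjusted p = 2.17e-06), as were the X-linked genes Kdm6a (-0.59), Kdm5c (-0.45) and Ddx3x (-0.48, limma adjusted p = 0.0208) and 2 predicted genes. The library labelled BCAA20 male replicate 6 had Xist at 154 FPKM and Ddx3y at 0. Xist was at most 0.154 FPKM in the other 11 male-labelled libraries and between 106 and 140 FPKM in the 12 female-labelled libraries. Sex comparisons keep the label of this library, and 11 genes passed without it. Without the 4 doubted libraries, of which it is 1, the log2 change of Xist was -7.74. Ddx3x lost its call when any of 10 libraries was left out, and both Ddx3x and Kdm5c lost theirs without the 4 doubted libraries (log2 changes -0.52 and -0.41, limma adjusted p = 0.058 and 0.128). Ddx3x also lost its call with regional marker scores as covariates (log2 change -0.46, limma adjusted p = 0.197). The X-linked and Y-linked genes named here include close paralogs of each other, whose values are uncertain where reads are shared.

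No gene passed the test of a sex difference in the response to BCAA200 against BCAA20 with limma, and 491 genes had an unadjusted p under 0.05. Micu3, a regulator of mitochondrial calcium uptake, had the lowest p among named genes (log2 difference 1.254, SE 0.262, limma adjusted p = 0.91), and a predicted gene the lowest of all (limma adjusted p = 0.0778). Micu3 passed without BCAA20 male replicate 5 (limma adjusted p = 0.0489) or BCAA200 female replicate 2 (limma adjusted p = 0.0486), and with array weights (log2 difference 1.47, limma adjusted p = 0.0121). Without BCAA20 male replicate 5, 2 genes passed, and without the library labelled BCAA20 male replicate 6 or BCAA200 female replicate 2, 1 passed. Within females no gene passed and 578 had an unadjusted p under 0.05, and within males none passed and 332 did, all with limma. Without BCAA200 female replicate 1, 1 gene passed in females, and without BCAA20 male replicate 5, 2 passed in males. With only the groups compared in the fit, 1 gene passed in females and 5 in males, and with array weights 1 in males.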

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

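The tests of Anapc4, of the sex label and of the lane were chosen after their results were seen. The regional covariates were added after the data were seen, with the bound on their result set before it was computed, and the splits of the samples were set before their results.

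Anapc4 lay between 10.9 and 12.6 FPKM in the 6 BCAA200 libraries. Of the other 18 libraries, 2 were at or near that level (BCAA20 female replicate 3 at 12.6 and BCAA50 female replicate 2 at 13.2) and the rest between 21.9 and 38.5. A lane effect as the whole cause is argued against within lane 1, where 10 of the 12 BCAA20 and BCAA50 libraries lay at 21.9 FPKM or above and the 95% interval of BCAA200 against BCAA20 ended at -0.54 (log2). The gene was picked after its values were seen, and its limma adjusted p in that comparison was 1, so this does not exclude chance. An estimate that jumps between levels may be the source: 475 genes jumped between 2 levels, and 324 with a stricter gap. At most 10 did in 20 simulated sets, which hold no sex or regional structure. Of the 475, 6 parted the libraries by sex profile and 16 by low Slc17a7, so the count is not one of quantification jumps alone. Jumps were associated with diet in 9 genes, and 94 of 100 shuffles of the diet labels gave as many. A measure drawn up after seeing Anapc4, all libraries of a diet on a side with at most 2 others, was met by 1 gene, and by as many in 4 of 100 shuffles, so such jumps and the diet cannot be told apart. The 2 other low libraries are also the 2 whose label holds a different field value, of unknown meaning, which is 1 of 153 pairs and was noticed in the data.

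The library labelled BCAA20 male replicate 6 had a female profile. A swap within the series is argued against, as 0 female-labelled libraries had Ddx3y above 1 FPKM. A mixture is argued against by a summed Y-linked level of 0.006 FPKM, below the 0.128 of the highest female-labelled library. A wrong sex label, or a swap with a sample outside the series, may account for it, with Xist at 154 FPKM. No biological explanation was tested.

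The 3 comparisons with BCAA100 gave a mean of 1218 genes at an unadjusted p under 0.05, against 399 for BCAA200 against BCAA20. With regional marker scores as covariates the mean was 653, under the 690 that chance gives, and the count of BCAA200 against BCAA20 was 725. In BCAA200 against BCAA100 the covariates widened the SE of Smox from 0.180 to 0.297 and that of Anapc4 from 0.204 to 0.266. A part of the fall can therefore come from lost precision. Without the 4 doubted libraries, 3 of them with low Slc17a7, the mean was 1207, so these libraries alone do not account for the excess and a part of the regional make-up stays open. The lane cannot be told apart from the diet, as 0 BCAA100 libraries were in lane 1.

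The real labelling is counted among the splits in all shares given here. Chance could not be excluded for the 2 genes of BCAA200 against BCAA100: 5 of 100 splits gave as many, the highest other 3. The same held for the 10 lists of BCAA200 against BCAA20 (5 of 100, median other 5, highest other 12) and of the dose trend (23 of 100, median other 7, highest other 16). For the 9 genes between the sexes, 2 of 100 splits gave as many, a share under the bound of 0.05 set beforehand. The other split that did so called 535 genes, so the count alone does not exclude chance. A split of BCAA50 and BCAA100 called 171 genes. Such high counts point to a structure of the samples. For results with 0 genes, all 100 splits gave as many, which was fixed in advance and says nothing about chance. The highest other count was 2 for BCAA200 against BCAA20, for both dose trends and for the sex difference of the response. It was 5 for BCAA20 against BCAA100. Within each sex 10 splits are too few for a share under 0.05, with 0 genes and a highest other of 1.

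Libraries far from the others were sought for 36 items, named genes and BCAA intake, in each of the 4 diets with 6 libraries. Of these 144 tests, 19 held such a library, where independent tests of normal values would give about 7. The items share libraries and can vary together, and FPKM values need not be normal, so the count does not show an excess. High values were Abcg2 6.25 FPKM and Bcat1 24.3 in BCAA20 female replicate 2, Bcat2 5.04 in BCAA20 female replicate 1, Agrp 0.865 in BCAA20 male replicate 4, and Cartpt 44.7 in the library labelled BCAA20 male replicate 6. They were also Plin4 3.53, Tph2 4.22 and Slc6a4 1.47 in BCAA50 female replicate 3, Cartpt 45.1 and Avp 169.3 in BCAA50 female replicate 1, and Anapc4 37.7 and Pomc 45.1 in BCAA100 male replicate 5. In BCAA200 male replicate 4 they were Agrp 0.393, Pomc 23.1, Tph2 7.30 and Slc6a4 1.95, and in BCAA200 male replicate 5 Mettl14 6.03. Low values were Hcrt, listed at 0 in BCAA100 male replicate 6, and Ppm1k 6.64 in BCAA20 female replicate 1.

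The response to BCAA200 against BCAA20 differed between the sexes for 9 lists by camera with the preset correlation, and for 0 with an estimated correlation. Higher in males relative to females were GABA signalling (adjusted p = 0.0136), heat shock (0.0406), cholesterol biosynthesis (0.0406) and oligodendrocyte markers (0.00826). Lower were interferon response (0.00141), nuclear oxidative phosphorylation (0.026), ribosomal proteins (0.000268), and microglia and endothelium markers (0.0175 each). The lowest adjusted p with an estimated correlation was 0.801. The library labelled BCAA20 male replicate 6, with its female profile, is 1 of the 3 BCAA20 males used here. These lists were not tested again without it.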

How the results depend on the processing

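The regional covariates and leaving out the doubted libraries were chosen after the data were seen. No result past its threshold changed direction under the alternatives run. Counts of genes moved as follows. BCAA200 against BCAA100 had 2 genes, 5 with median-of-ratios scaling, 5 with only the groups compared, 0 with regional covariates and 49 without the doubted libraries. BCAA20 against BCAA100 had 2 with only the groups compared and 5 without the doubted libraries, BCAA50 against BCAA100 19 without them, and the sex difference of the response 1. With only the groups compared, 1 gene passed in females and 5 in males. With array weights, 1 passed in the lane 1 trend, 2 in the sex difference of the response and 1 in males, and Smox no longer passed in BCAA200 against BCAA100 (log2 change 1.08, adjusted p = 0.071). Lists went from 10 to 0 with an estimated correlation and 0 with fry in both comparisons, and to 4 (BCAA200 against BCAA20) and 5 (trend) with regional covariates. The trend had 4 lists at a mean of at least 5 FPKM and 6 with all 4 diets. The cause of these changes was not tested.

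Leaving out each library in turn gave 0 to 1 genes for BCAA200 against BCAA20, for both dose trends and in females, 0 to 2 for BCAA20 against BCAA100, in males and for the sex difference, 0 to 23 for BCAA50 against BCAA100, 0 to 41 for BCAA200 against BCAA100 and 8 to 11 between the sexes. Lists ranged from 1 to 10 and, in the trend, from 2 to 10. BCAA200 against BCAA100 had 0 genes without BCAA100 female replicate 1 or 3, BCAA200 female replicate 1, or BCAA200 male replicate 4, 5 or 6, and 41 without BCAA50 female replicate 1. The trend had 2 lists without BCAA200 female replicate 3, 3 without BCAA200 female replicate 1 or male replicate 6, and 4 without BCAA20 female replicate 1 or male replicate 4.

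Replicate numbers did not pair the libraries: deviations of same-numbered libraries had a median correlation of 0.019 over 36 pairs, and 7 of 24 libraries correlated best with their own number. With the replicate block, BCAA200 against BCAA100 had 2 genes, the lists 9 and 10, and the other diet counts 0; Smox no longer passed (adjusted p = 0.239). A block could not be fitted between the sexes, which share no numbers. The fit on only the groups compared was not run for the 4-diet trend and the sexes, which use all groups, and a count model was not applicable. The depth of the libraries is unknown, so its limit on genes of low level such as Agrp could not be given.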

Other observations

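The relations of Ttc7b with intake were chosen after its result was seen. In males relative to females, camera with the preset correlation called 7 lists, 4 up and 3 down, and 0 with an estimated correlation (lowest adjusted p = 0.713). Cytosolic ribosomal proteins had 71 of 79 members above 0 and nuclear oxidative phosphorylation 68 of 74 (camera adjusted p = 8.74e-06 for both). Oligodendrocyte and myelin markers had 16 of 16 above 0 (camera adjusted p = 0.00139) and interferon response genes 15 of 16 (camera adjusted p = 0.0478). Immediate early genes had 18 of 20 below 0 (camera adjusted p = 0.000194). Each of these had an adjusted p = 0.904 with an estimated correlation. Glucocorticoid response genes had 16 of 16 members below 0 (camera adjusted p = 8.74e-06; adjusted p = 0.713 with an estimated correlation). Cortex and hippocampus markers had 12 of 14 members below 0 (camera adjusted p = 0.000677; adjusted p = 0.904 with an estimated correlation), and 2 of the 3 libraries with low Slc17a7 are male.

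Within diets, Ttc7b, the gene with the lowest p in the authors' deposited table, had Pearson correlations with intake of -0.421 on BCAA20, -0.631 on BCAA50, -0.356 on BCAA100 and 0.674 on BCAA200 (n = 6 each, Spearman -0.348, -0.696, -0.371 and 0.6). The exact permutation p were 0.389, 0.164, 0.46 and 0.15 for Pearson and 0.511, 0.144, 0.497 and 0.242 for Spearman, and the adjusted p of the former at least 0.656 over 12 relations. Without the 2 animals farthest from the median intake, Pearson correlations were -0.893, -0.61, 0.856 and 0.127, and no relation within a diet passed the adjustment.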
